A study of Homo sapiens with 32 samples.

How the data were processed

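Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where TEAD4 sat in the genome of 4 human cancer cell lines. TEAD4 is a DNA-binding transcription factor of the TEA domain family, and YAP is a transcriptional co-activator that has no DNA-binding domain of its own and reaches chromatin through TEAD proteins. Y79 and WERI-RB1 are retinoblastoma lines, and NCI-H209 and NCI-H2171 are small cell lung cancer (SCLC) lines. Each line was transduced with an empty vector or with YAP. Per the labels, Y79 received wild-type YAP and the other 3 lines received YAP-5SA, a mutant described as overactive. Cells were collected 5 days after transduction, crosslinked with formaldehyde and sonicated, and the DNA was precipitated with an antibody against TEAD4. Libraries were amplified with 18 PCR cycles and selected for fragments near 300 bp, between 239 and 361 bp, per the labels' protocols. The labels list 32 samples in all. The 16 TEAD4 libraries, 2 per vector and line, were analysed, and the 16 input samples were not used here.

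For each TEAD4 library the authors deposited a peak list with 6 columns (chromosome, start, end, peak number, score and strand), so peaks were called per library and replicates were not pooled. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.32, FastQC, Bowtie2 and HOMER 4.10 and the genome build was hg19 (GRCh37). The positions fit that build, since peaks on chromosome 1 reach base 249212711, past the end of that chromosome in GRCh38. The peak-calling settings, the use of the input libraries and any blacklist filter are not given in the sources used here. The deposited score of a peak is the authors' own value and behaves as a number of sequence tags scaled to a fixed library total. In every library 100% of the scores below 10 lay on whole multiples of a single step, within a tolerance of 0.0075 score units, and that step is what 1 tag is worth in the library. The fixed total is not stated, so only relative depth could be recovered. Scores were used to rank peaks within a list, to filter them by a threshold, and to describe them, and ratios and means of scores over libraries are descriptions of these libraries without a test.

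Relative depth ran from 1.00 in NCI-H2171 YAP-5SA replicate 2 to 2.41 in NCI-H209 empty-vector replicate 1. The weakest peak of a library held 7 to 12 tags and the median peak 12 to 20 tags, so the presence of weak peaks carries a large counting error. PCR duplicates cannot be told from separate molecules in the peak lists, and intervals given here cover counting error only.

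All peaks on chromosomes 1 to 22 and X were used. The 20 peaks on chromosome Y, of 187757 peaks in all libraries, were left out. Within each line, peaks of the 4 libraries that overlapped by at least 1 bp were merged into regions. A region was called gained when it held a peak in both YAP libraries and in neither empty-vector library, lost in the opposite case, and kept when all 4 libraries held a peak. The same merging over all 16 libraries gave the regions that were compared across lines, and because merging over more libraries joins some neighbours, the per-line counts differ slightly between both sets.

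Peak numbers of YAP and empty-vector libraries were compared on the log2 scale with an exact two-sided permutation test that exchanged libraries within lines only, over 1296 arrangements. For each merged region, the number of YAP libraries with a peak was tested with an exact two-sided test given the total of each line, with Benjamini-Hochberg adjustment over the regions whose smallest attainable p was at most 0.01, and an adjusted p of at most 0.05 was called. Within a single line, 2 libraries against 2 cannot give an exact p below 0.333, so lines are reported as values. Sharing of gained regions between lines was set against the number for independent lists among the merged regions of both lines, with a 95% Poisson interval for the observed number. The region test was checked on simulated data with the 608 testable regions and their line totals. Of 200 regions given an odds ratio of 50 for YAP, 84.0% were called, with 7 calls among the others, and 0 regions were called when none was changed. Apart from that odds ratio, the simulation gave all libraries of a line the same chance of a peak. It therefore does not check calls that arise from lists of unequal length, and the region test takes no account of list length either.

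The tests of peak number and of single regions, the region definitions and the rule for named regions were fixed before the data were examined. The comparisons of depth and of the tumour kinds, the Poisson intervals for sharing, the regions of a single tumour kind and the values by number of lines gained or by presence in another line were added afterwards. The rule takes, per line, the first 12 gained and the first 4 lost regions by mean rank of the score in the libraries that hold them, and over lines the first 20 called regions by p, number of lines gained and mean rank. The 13 gene lists fixed with it, together with gene-level, promoter and motif comparisons, need an annotation and a sequence of hg19. The gene table at hand is on GRCh38, so none of these was run and regions are named by position. Positions are 1-based hg19 coordinates. Other settings fixed with them were a stricter score threshold (6.74, the median score of all peaks), base pairs covered in place of peak number, a reciprocal overlap of 50% of each peak, lists of equal length within a line, a looser filter on testable regions (0.05), a replicate block, and leaving out each library. Leaving out each line, and sharing and replicate overlap at equal list length, were added after seeing the data. A test of kept-region scores across lines, tried after seeing the data, is left out because scores are used here for description only. The sources do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No batch or date is given in the sources used here. Wild-type YAP was used in Y79 only, so the form of YAP and the line cannot be separated. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.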

Results

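TEAD4 binding was mapped in 2 retinoblastoma lines, Y79 and WERI-RB1, and in 2 SCLC lines, NCI-H209 and NCI-H2171. Each line carried an empty vector or YAP, with 2 libraries per group, which makes 16 TEAD4 libraries in 8 groups. The design asks where TEAD4 binds once YAP is supplied to cells of tumour kinds in which YAP is commonly silent. The deposited lists held 187757 peaks, each of a width fixed per library between 140 and 186 bp. Replicate lists overlapped more with YAP than with the empty vector in each line. The share of the shorter list found in the other replicate was 84.2% with YAP and 33.5% with empty vector in Y79, 59.7% and 47.8% in WERI-RB1, 54.8% and 23.1% in NCI-H209, and 54.5% and 22.8% in NCI-H2171. This share depends on list length, and with lists of equal length within a line it was 73.3% and 32.0% in Y79, 51.4% and 48.5% in WERI-RB1, 73.9% and 22.4% in NCI-H209, and 47.3% and 16.99% in NCI-H2171.

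YAP libraries held more TEAD4 peaks than empty-vector libraries. In Y79, the empty-vector libraries held 734 and 591 peaks and the YAP libraries 4285 and 14028, a ratio of means of 13.8 ± 10.6 (SD, n = 2 per group). NCI-H209 rose from 5409 and 3024 peaks to 21989 and 16564, a ratio of 4.57 ± 2.04, with no overlap between the groups. In NCI-H2171 the lists held 5208 and 14186 peaks with empty vector and 32987 and 13945 with YAP-5SA, a ratio of 2.42 ± 2.11 in which the ranges overlap. WERI-RB1 already held 12296 and 11535 peaks with empty vector, against 10917 and 20039 with YAP-5SA, and its ratio of 1.30 ± 0.54 lies within the spread between replicates.

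Over the 4 lines the mean log2 ratio was 1.86, a 3.62-fold difference, with p = 0.00926 in the exact two-sided permutation test, where the smallest p possible is 0.00154. Depth did not account for a difference of this size in the libraries, since relative depth differed by -0.03 on the log2 scale (exact permutation p = 0.769). The retinoblastoma lines had a mean log2 ratio of 1.93 and the SCLC lines of 1.78, and the difference of 0.16 was not tested, with 2 lines of each kind. The test rests on few lines. Without Y79 the log2 ratio was 1.29 and without NCI-H209 it was 1.73, each with an exact permutation p of 0.0556, while without WERI-RB1 YAP-5SA replicate 2 the ratio of that line turned to 0.916.

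**Figure D1:**
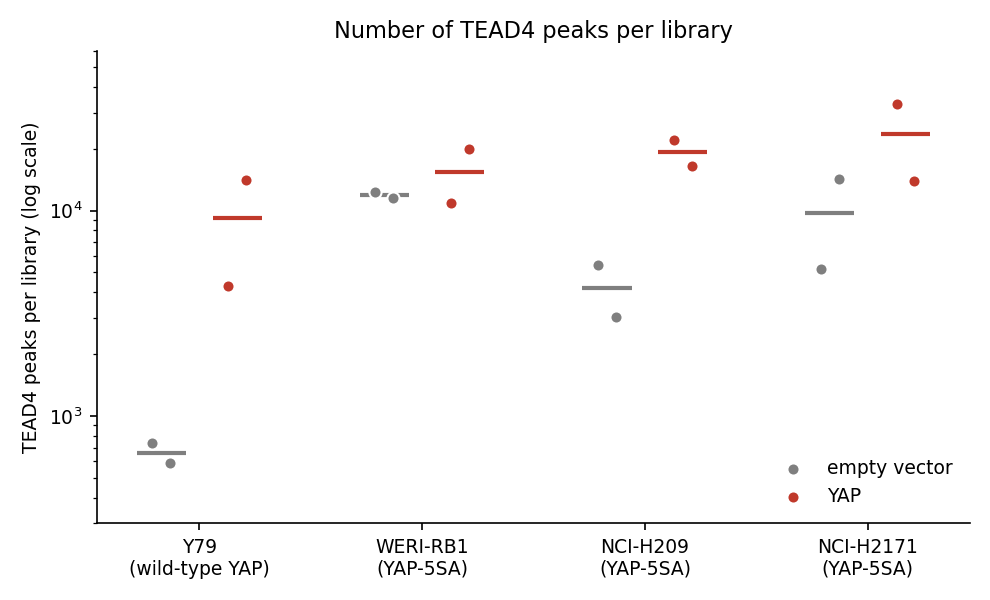
Number of TEAD4 peaks per library (log axis) for the 4 lines; points are single libraries and bars the means of 2 libraries. The groups are apart in Y79 and NCI-H209, from 591 to 734 against 4285 to 14028 peaks and from 3024 to 5409 against 16564 to 21989, and overlap in WERI-RB1 and NCI-H2171.

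A common set of regions held TEAD4 with YAP in all lines. Over the 16 libraries, 115425 merged regions were found, and 67.1% of them held a peak in a single library. Of these, 123 regions were gained in all 4 lines, with a peak in each of the 8 YAP libraries and in none of the 8 empty-vector libraries. Independent lists drawn from all 115425 regions would give 0.337. Regions with a peak in a single library cannot be gained, so this number is lower than it would be among regions that could be. A further 426 regions were gained in 3 lines, 1847 in 2 lines and 14855 in 1 line. No region was lost in more than 1 line, and none held a peak in all 16 libraries.

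The exact test with Benjamini-Hochberg adjustment called 544 of 608 testable regions as holding a peak more often with YAP, with adjusted p from 0.00763 to 0.0293. It called 0 regions less often with YAP, and 0 also at an unadjusted exact p under 0.05. A region lost in a single line cannot reach the threshold, so the 2449 regions of that kind were outside this test. All called regions were gained in 3 lines (421) or in all 4 (123), and a call the other way would need losses in about as many lines. Lost regions numbered 0 in Y79, 112 in NCI-H209 and 137 in NCI-H2171, so such calls were hardly possible. The 0 calls therefore say little about direction. Of the 544 regions, 494 held no peak in any empty-vector library and 50 held at least 1. Chromosomes 1, 2 and 3 carried the most, with 64, 50 and 44 regions. These counts were not set against the testable regions of each chromosome, so they show no preference for any chromosome. The number of calls changes with the filter and the list length: 1403 of 1841 testable regions with the looser filter, 155 of 169 with lists of equal length, and 178, 174 and 199 without WERI-RB1, NCI-H209 and NCI-H2171. Leaving out a library makes more regions testable, and calls rose to 854, 842 and 830 without WERI-RB1 empty-vector replicates 1 and 2 and YAP-5SA replicate 1, and to 923, 884 and 924 without NCI-H2171 empty-vector replicates 1 and 2 and YAP-5SA replicate 2. In each of these settings, 0 regions were called less often with YAP.

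Among the 123 regions gained in all 4 lines, which share the smallest p, the best mean rank in the YAP libraries was that of chr3:134045812-134046011, with a mean peak score of 38.7 ± 16.6 (SD, n = 8). Among these it was followed by chr1:19379027-19379218 with 37.0 ± 15.7, chr8:127592185-127592397 with 43.7 ± 28.2 and chr2:151267488-151267693 with 30.4 ± 15.4. All 20 named regions held a peak in 8 of 8 YAP libraries and 0 of 8 empty-vector libraries, with an exact p of 0.00154, the smallest possible, and an adjusted p of 0.00763. The next were chr15:57844015-57844226, chr19:45879674-45879879, chr6:30811930-30812122 and chr3:58546533-58546771, with mean scores of 27.2, 28.8, 26.5 and 25.1. Then came chr20:60936939-60937161, chr11:8939099-8939306, chr1:207180784-207180988 and chr1:29598279-29598484, with 29.2, 22.5, 32.8 and 24.4. The regions chr11:118486105-118486300, chr22:30603004-30603209, chr19:2540798-2541022 and chr1:40358862-40359095 had mean scores of 24.7, 22.8, 27.7 and 28.8. The last of the 20 were chr15:57648942-57649154, chr7:46185093-46185282, chr10:104990996-104991257 and chr2:62899918-62900125, with 22.99, 28.6, 22.9 and 28.0. The lowest score of any of the 20 regions in a YAP library was 9.41, above the median score of each YAP library, which ran from 6.18 to 8.5. With lists of equal length, chr7:46185093-46185282 alone of the 20 was no longer called. The region on chromosome 8 lies beside a segment of NCI-H2171 in which nearly all peaks had very high scores, described with that line.

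**Figure D2:**
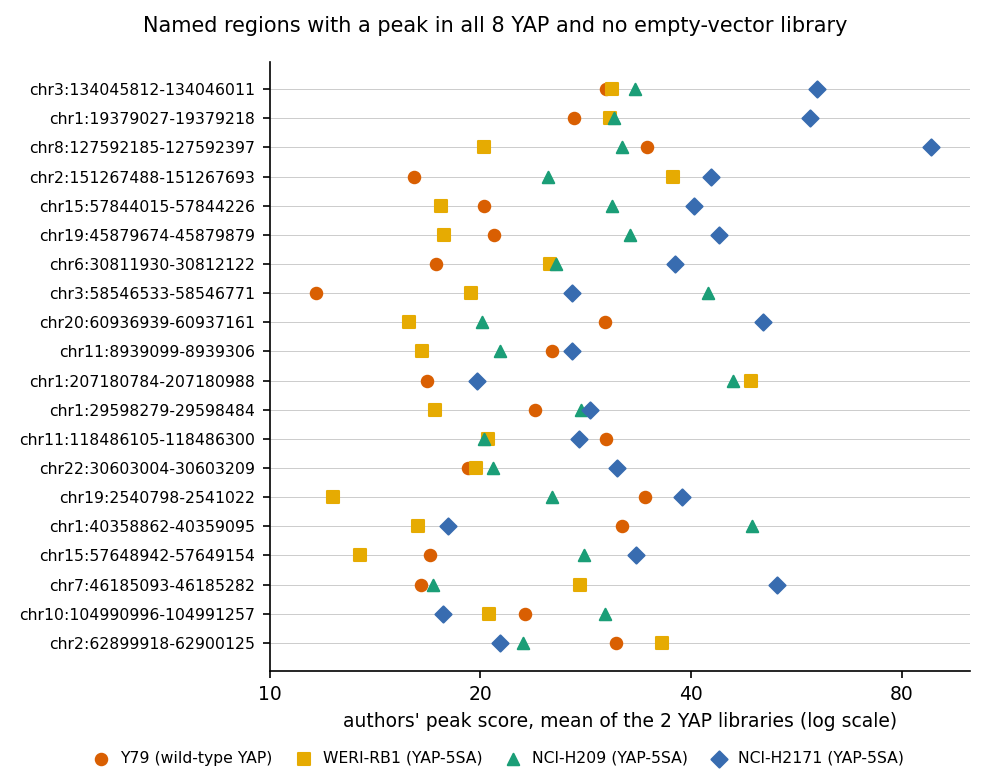
The 20 named regions (hg19) with a peak in all 8 YAP libraries and in no empty-vector library. The horizontal log axis gives the authors' peak score as the mean of the 2 YAP libraries of each line, one symbol per line; scores are scaled within a library, and the highest mean is 88.0, in NCI-H2171 on chromosome 8.

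In Y79, wild-type YAP gave 3011 gained regions and 0 lost regions, with 192 kept among 15083 merged regions. The other 2 ways of dividing the 4 libraries into pairs gave at most 89 such regions. Each of those pairs holds an empty-vector library, so its count cannot exceed that list, of 734 or 591 peaks here. List length alone thus kept the other pairings below the number gained in Y79, and it limits them in the other lines too. Of the gained regions, 6 stood apart by score. They were chr2:16245804-16245990 with 135 ± 7.8 (SD, n = 2), chr18:74374583-74374773 with 129 ± 8.8, chr2:15888002-15888216 with 108 ± 11.3, chr18:44133021-44133213 with 105 ± 11.9, chr18:43733004-43733207 with 101 ± 10.3 and chr2:15941084-15941272 with 85.9 ± 0.57. The next was chr8:118859919-118860114 with 53.6 ± 7.5, followed by chr13:111137931-111138137 with 51.0 ± 15.9 and chr15:67127399-67127584 with 47.7 ± 11.2. The named regions ended with chr6:43970009-43970206, chr3:126569647-126569833 and chr7:39773618-39773840, with scores of 44.5, 41.6 and 39.5. The median score in these YAP libraries was 7.37 and 6.95.

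In WERI-RB1, YAP-5SA gave 3977 gained and 2206 lost regions, with 1601 kept among 36637, and the other ways of pairing the libraries gave at most 768. Gained regions were led by chr1:207180812-207180975 with a score of 48.7 ± 8.6 (SD, n = 2), chr1:203954330-203954479 with 45.9 ± 11.2, chr1:144941329-144941480 with 44.7 ± 6.6 and chr1:151519613-151519758 with 45.2 ± 15.3. A gained region on chromosome 13, chr13:111137961-111138106 with 41.0 ± 9.3, overlaps the region named there in Y79. The other named regions were chr2:44473673-44473830, chr3:76546932-76547094, chr2:62899948-62900095, chr18:26745369-26745514, chr11:121909368-121909552, chr1:205113980-205114147 and chr2:151267519-151267666, with scores from 36.3 to 42.4. Lost regions had lower scores in the empty-vector libraries: 31.5 ± 1.8 at chr1:205433094-205433239, 31.3 ± 4.1 at chr16:70973412-70973578, 27.1 ± 4.9 at chr1:217016929-217017089 and 26.2 ± 1.6 at chr1:165540134-165540287. Lost regions made up 35.7% of gained and lost regions together, against 0%, 1.4% and 2.4% in Y79, NCI-H209 and NCI-H2171, and this difference between lines was not tested. The share depends on single libraries: without empty-vector replicate 1 or 2 it was 60.7% or 62.9% in WERI-RB1, 6.2% or 4.8% in Y79, 17.9% or 29.5% in NCI-H209 and 62.2% or 28.1% in NCI-H2171. Without YAP replicate 1 or 2 it was 14.9% or 31.9% in WERI-RB1, 0% or 0.2% in Y79, 1.8% or 0.8% in NCI-H209 and 4.5% or 0.6% in NCI-H2171.

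In NCI-H209, YAP-5SA gave 7740 gained and 112 lost regions, with 394 kept among 34506, and the other ways of pairing gave at most 578. With empty-vector lists of 5409 and 3024 peaks, those pairings could not have reached the number gained. The gained region of highest rank was chr3:112366102-112366257 with a score of 86.0 ± 12.9 (SD, n = 2). Next came chr3:108192682-108192851 with 67.5 ± 10.2, chr3:110918977-110919132 with 65.3 ± 14.5 and chr9:2180799-2180963 with 66.0 ± 11.2. They were followed by chr8:94892562-94892717, chr8:75916461-75916616, chr14:33706463-33706624 and chr3:105554598-105554754, with scores of 58.9, 58.3, 56.9 and 55.4. The last named were chr2:5989863-5990019, chr4:19031753-19031908, chr1:40573326-40573487 and chr3:113741202-113741381, with 55.9, 54.4, 55.9 and 55.8. The lost regions chr20:52483970-52484123, chr8:73636038-73636262, chr8:68412183-68412367 and chr4:74456348-74456536 had scores of 15.95, 14.7, 14.3 and 13.3 in the empty-vector libraries.

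In NCI-H2171, YAP-5SA gave 5541 gained and 137 lost regions, with 671 kept among 51813, and the other ways of pairing gave at most 1123. The lost regions were thus fewer than another pairing gave. In kept regions, empty-vector replicate 1 correlated more with YAP-5SA replicate 1 (r = 0.67) than with empty-vector replicate 2 (r = 0.31). Replicates of this line therefore differed in more than the vector. Of the first 5 gained regions, 4 lay between 128 and 129 Mb of chromosome 8. They were chr8:128931453-128931610 with a score of 132 ± 23.2 (SD, n = 2), chr8:128822445-128822596 with 141 ± 38.7, chr8:128653087-128653240 with 125 ± 31.5 and chr8:128383666-128383821 with 81.9 ± 20.6. The remaining region of the 5 was the nearby chr8:127592197-127592352 with 88.0 ± 8.1, which lies inside the region named over all lines. In that window, 22 of 24 peaks of YAP-5SA replicate 1 and 8 of 8 peaks of replicate 2 scored above the 95th percentile of their library, and the single peak there in each empty-vector library scored 115 and 88.7. Elsewhere, gained regions were named at chr12:461735-461888, chr14:23041575-23041736, chr14:23083203-23083387, chr8:64187515-64187691, chr14:23276821-23276982, chr12:28177242-28177409 and chr3:134045840-134045992, with scores from 60.6 to 80.8. The lost regions chr5:10288798-10288988, chr1:201662219-201662377, chr2:195197921-195198115 and chr11:46694192-46694375 had scores of 13.0, 12.1, 11.5 and 11.3.

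The counts depend on both libraries being required, and a left-out library leaves a group in which a single peak is enough. Without YAP replicate 1 or 2, gained regions numbered 13286 or 3685 in Y79, 14746 or 7575 in WERI-RB1, 14877 or 19676 in NCI-H209 and 10769 or 28486 in NCI-H2171. Without empty-vector replicate 1 or 2, lost regions numbered 219 or 157 in Y79, 7041 or 7410 in WERI-RB1, 1831 or 3349 in NCI-H209 and 10211 or 2462 in NCI-H2171, which exceeds the gained regions in WERI-RB1 in both cases and in NCI-H2171 without replicate 1. Without a YAP library, lost regions moved to 6 in Y79 (replicate 2), 3550 in WERI-RB1 (replicate 2), 269 in NCI-H209 (replicate 1) and 503 in NCI-H2171 (replicate 1). Kept regions moved to 312 or 475 in Y79 and 671 or 1075 in NCI-H209 without empty-vector replicate 1 or 2, and to 2942 in WERI-RB1 without YAP-5SA replicate 1. In NCI-H2171 they moved to 1434 or 1313 without empty-vector replicate 1 or 2 and to 1033 without YAP-5SA replicate 2. With lists of equal length, gained and lost regions numbered 203 and 26 in Y79, 3351 and 2495 in WERI-RB1, 1694 and 357 in NCI-H209 and 1676 and 315 in NCI-H2171.

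**Figure D3:**
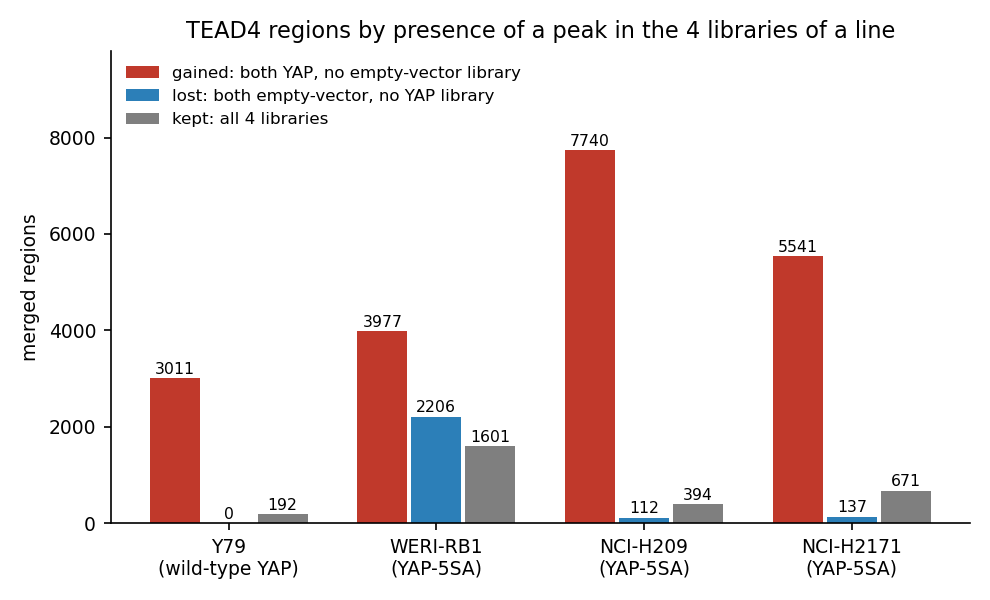
Number of merged regions gained, lost and kept in each line, as bars from 0 with the count above each bar. Gained regions exceed lost regions in every line, by the smallest margin in WERI-RB1 with 3977 against 2206.

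**Figure D4:**
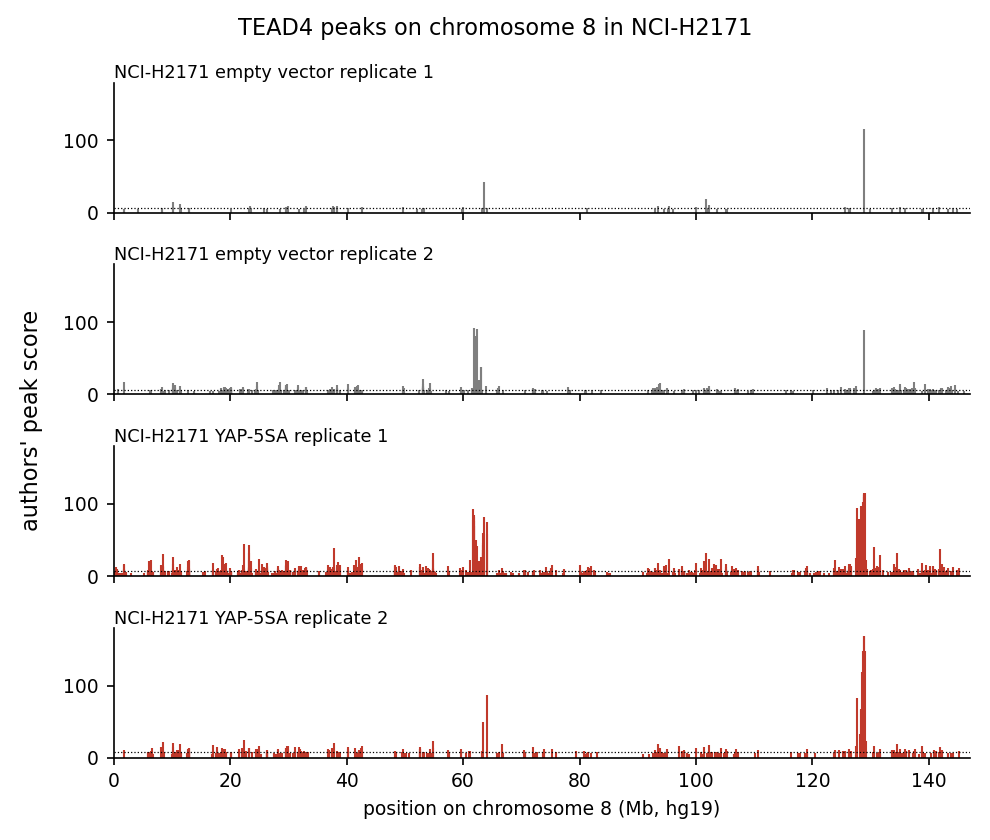
TEAD4 peaks along chromosome 8 (Mb, hg19) in the 4 NCI-H2171 libraries; the height of each line is the authors' peak score and the dotted line the median score of the library. Between 128 and 129 Mb, peaks reach 115 and 88.7 in the empty-vector libraries and 116 and 169 in the YAP-5SA libraries, against library medians of 5.65, 6.49, 6.37 and 8.5.

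Gained regions were shared between lines more than independent lists would be in 5 of the 6 pairs of lines. WERI-RB1 and NCI-H2171 shared 704 gained regions where 269 would be shared by independent lists, a ratio of 2.62 (95% Poisson interval 2.43 to 2.82). The ratio was 1.98 (1.86 to 2.10) for the SCLC lines, which shared 1077, and 1.96 (1.80 to 2.14) for the retinoblastoma lines, which shared 517. WERI-RB1 and NCI-H209 shared 859, a ratio of 1.87 (1.74 to 2.00), and Y79 and NCI-H2171 shared 356, a ratio of 1.33 (1.19 to 1.47). Y79 and NCI-H209 shared 350 where 488 would be shared by independent lists, a ratio of 0.717 (0.643 to 0.796). With lists of equal length that ratio turned to 1.09, and those of Y79 with WERI-RB1 and with NCI-H2171 were 3.30 and 2.13. The intervals cover counting error only, regions are not independent replicates, and the number for independent lists falls with the number of regions found in a single library.

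Some regions were gained in both lines of a tumour kind with no peak in any library of the other kind. This held for 127 of the 517 regions gained in both retinoblastoma lines (24.6%) and for 403 of the 1077 gained in both SCLC lines (37.4%). Matching shares for pairs of lines of different kinds were not computed, so these shares do not show that the regions belong to a tumour kind. Among the first, chr2:227289861-227290048 had a mean score of 28.5 ± 8.4 (SD, n = 4), chr6:130268013-130268202 of 18.0 ± 4.1 and chr7:137811746-137811931 of 18.4 ± 5.2. Among the second, chr10:13771180-13771351 had 33.5 ± 10.3, chr12:110477030-110477200 had 30.5 ± 7.6 and chr14:98536307-98536464 had 34.3 ± 12.8. These 6 regions were chosen by mean rank after their values were seen, and the tumour kinds were not tested for single regions.

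Kept regions, which held TEAD4 with and without YAP, had different scores by line. In Y79 the median log2 ratio of YAP over empty-vector scores was 1.44, and 100% of the 192 kept regions scored higher with YAP. The median log2 ratio was 0.50 in NCI-H209 and 0.56 in NCI-H2171, with 81.2% and 87.0% of kept regions higher with YAP-5SA. In WERI-RB1 it was -0.26, and 36.4% were higher. These ratios describe libraries whose scores are each scaled to a fixed total and were not tested. Leaving out a library moved the ratio to 0.14 and 0.76 in NCI-H209 (without YAP-5SA replicate 1 and empty-vector replicate 1). It moved to 0.24 and 0.94 in NCI-H2171 (without empty-vector replicates 1 and 2). In WERI-RB1 it moved to -0.48 and -0.088 (without YAP-5SA replicate 2 and empty-vector replicate 1).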

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

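The shares of lost regions without single libraries were computed only after the other shares had been seen. Some regions moved in opposite directions in 2 lines, with a peak in both empty-vector libraries and no YAP library of the first line, and the reverse in the second. The difference between lines was not tested for single regions. There were 54 regions lost in WERI-RB1 and gained in Y79, where independent lists would give 145, and 3 and 5 regions lost in WERI-RB1 and gained in NCI-H209 and NCI-H2171. There was 1 region lost in NCI-H209 and gained in Y79, and 2 lost in NCI-H209 and gained in NCI-H2171. There were 2 regions lost in NCI-H2171 and gained in Y79, and 1 lost in NCI-H2171 and gained in NCI-H209. All of these numbers lie below those of independent lists. The lists include regions found in only 1 of the 2 lines, which cannot be in both, and lost regions were seldom found in another line. The shortfall therefore cannot be read as avoidance of opposite moves.

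In WERI-RB1, lost regions made up 35.7% of gained and lost regions against 0% to 2.4% in the other lines, but without single libraries the share ranged from 14.9% to 62.9% in WERI-RB1, from 0% to 6.2% in Y79, from 0.8% to 29.5% in NCI-H209 and from 0.6% to 62.2% in NCI-H2171, since a group of 1 library needs only that library. With only peaks scoring at least 6.74 the share was 42.6% in WERI-RB1, so it does not rest on the weakest peaks alone. That cut only sets a new threshold, so it cannot tell whether peaks near a threshold are the cause. The median best score was 8.66 for lost, 9.86 for gained and 16.8 for kept regions of this line. The similar lengths of the lists with and without YAP in this line may account for part of the share. With lists of equal length within each line, the highest share of the other lines was 17.4%, against 42.7% in WERI-RB1. That value lies between the bounds set for the test, so list length and a property of the line cannot be told apart here, and a biological difference between the lines stays open and was not tested.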

How the results depend on the processing

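The settings that leave out a whole line, and sharing and replicate overlap at equal list length, were chosen after seeing the data; the rest were planned. The higher peak number over 4 lines kept its direction and stayed past the threshold with the stricter score threshold, with base pairs covered and without any single library (log2 1.64 to 2.07). It missed the threshold without Y79 (1.29) and without NCI-H209 (1.73), where 3 lines were left.

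With the stricter score threshold, the NCI-H209 peak ratio was 9.40. Gained regions numbered 1994 in Y79 and 2443 in WERI-RB1, lost regions 51 in NCI-H209 and 30 in NCI-H2171, and kept regions 102 in Y79 and 365 in NCI-H2171. With lists of equal length, there were 203 gained and 26 lost regions in Y79, 1694, 357 and 219 gained, lost and kept in NCI-H209, and 1676, 315 and 290 in NCI-H2171, fewer peaks entering by construction. Sharing of gained regions became 3.30 for Y79 and WERI-RB1, 2.13 for Y79 and NCI-H2171, and turned from below to above 1, to 1.09, for Y79 and NCI-H209; the cause was not tested. Reciprocal overlap moved no count by more than 1.5 times.

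Leaving out each library gave peak ratios of 6.47 to 21.2 in Y79, 0.916 to 1.68 in WERI-RB1 (below 1 without YAP-5SA replicate 2, the cause was not tested), 3.56 to 6.38 in NCI-H209 and 1.44 to 4.51 in NCI-H2171. Gained regions ranged from 3131 to 13286, 4366 to 14746, 8019 to 19676 and 6193 to 28486 in these lines, lost regions from 0 to 219, 2574 to 7410, 161 to 3349 and 179 to 10211, and kept regions from 192 to 475, 1964 to 2942, 433 to 1075 and 707 to 1434. These counts grow because a group of 1 library needs only that library. Kept-region score ratios ranged over 0.99 to 1.77, -0.48 to -0.088, 0.14 to 0.76 and 0.24 to 0.94 (log2).

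The regions called more often with YAP numbered 1403 with the looser filter, 155 with equal list length, and 178, 174 and 199 without WERI-RB1, NCI-H209 and NCI-H2171, and 579 to 924 without single libraries, where all 544 were called again and more regions became testable. The 494 called regions without an empty-vector peak keep an exact p under 0.01 whichever library is left out. These repeat calls therefore say little about dependence on single libraries. Of the 20 regions named over lines, chr7:46185093-46185282 alone lost its call, at equal list length, where YAP libraries with a peak exceeded empty-vector libraries by 6. None of these settings called a region less often with YAP, though too few regions were lost in most lines for many such calls.

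Libraries of equal replicate number were treated as pairs in a replicate block. Deviations of same-numbered libraries in kept regions correlated by 0.12 in Y79, -0.02 in WERI-RB1, 0.06 in NCI-H209 and 0.58 in NCI-H2171, so same-numbered libraries deviated together in NCI-H2171 but not in every line, and the numbers were not taken as pairs. With the replicate block, 123 regions were called, all that this block leaves testable, and all were among the 544; the peak number kept its log2 ratio of 1.86 (exact permutation p = 0.0313). The gene, gene-list, motif and promoter alternatives were not run. Depth limits the weakest peaks, of 7 to 12 tags, whose presence in a library is uncertain.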

Other observations

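The tests on depth, on the immunoprecipitation and on the chromosome 8 window were chosen only after their results, or values close to them, had been seen. Regions gained in more lines also had the higher median score within each line. From regions gained in 1 line to those gained in all 4, the median score in the YAP libraries went from 8.93 to 11.7 in Y79, from 7.71 to 16 in WERI-RB1, from 9.07 to 15.6 in NCI-H209 and from 9.47 to 25 in NCI-H2171. In Y79 the median was already 11.3 for regions gained in 3 lines. Their median rank there, at 20.5% of the list, was slightly better than the 21.5% of regions gained in all 4. Gained regions held a peak in another line more often than regions found in a single library of the line. The shares were 78.1% and 46.5% in Y79, 60.3% and 22.3% in WERI-RB1, 43.7% and 18.7% in NCI-H209, and 49.9% and 17.9% in NCI-H2171. Kept regions also exceeded single-library regions, at 96.4% in Y79, 55.6% in WERI-RB1, 33.6% in NCI-H209 and 47.7% in NCI-H2171. Their share lay above that of gained regions in Y79 and below it in the other lines, so the trait is not particular to gained regions. Lost regions were seldom found in another line, at 17.4% of 2202 in WERI-RB1, 18.9% of 111 in NCI-H209 and 11.8% of 136 in NCI-H2171.

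The regions called over the 4 lines all went one way, 544 more often with YAP against 0, though too few regions were lost for calls the other way. Of 100 divisions of the libraries within lines, drawn from 648, only the real one (1) called as many, and the highest of the others called 0. Among the divisions drawn, the calls thus followed the real one. Divisions that were not drawn may still call regions. Called regions without a peak in Y79, for example, keep their exact p when Y79 alone is divided differently. The divisions cannot tell YAP from any other difference between the 2 groups of libraries. At equal list length, 100% of the called regions were more often with YAP. With a single score threshold for all libraries, 383 were called. These calls cannot decide on longer lists or deeper sequencing, since few regions could be called the other way. At equal length, lost regions made up 11.4% of gained plus lost ones in Y79, 42.7% in WERI-RB1, 17.4% in NCI-H209 and 15.8% in NCI-H2171. Gained regions thus outnumbered lost ones in every line without longer lists, but empty-vector replicates also overlapped less there. Relative depth differed by only -0.03 on the log2 scale, which argues against deeper sequencing as the whole cause. A weaker precipitation from empty-vector cells is argued against as the whole cause by WERI-RB1: of the 178 regions called in the other 3 lines, 87.1% had more YAP than empty-vector libraries with a peak in WERI-RB1, and with the WERI-RB1 lists at equal length the share was 86.0%, with 1 region that had fewer. A weaker precipitation within the other lines was not tested, and whether YAP brings TEAD4 to these sites or holds it there was not tested either.

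In NCI-H2171, the window from 128 to 129 Mb of chromosome 8 held 22 and 8 of the 200 highest-scoring peaks of the YAP-5SA libraries, while in the other 3 lines no window held more than 4 in any library. Extra copies of this segment may raise every score within it, and NCI-H2171 is known to carry amplified MYC, a gene on the long arm of that chromosome. The window was picked for its top peaks, and of the 2 peaks outside the top 200 in the YAP-5SA libraries 0 (0%) scored above the 95th percentile, too few to decide. More copies of this segment and clustered strong binding cannot be told apart here, and the input libraries were not used here. Y79, known for amplified MYCN on the short arm of chromosome 2, had 3 of its 6 highest-scoring gained regions between 15 and 17 Mb of chromosome 2.

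Whether the regions called over 4 lines cluster along the genome was examined with 1 Mb windows. No window held more than 3 of them, and 0.994 of 10000 random draws of as many regions from all merged regions had a window with at least as many, so no clustering was seen beyond the density of all peaks.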
